A study of Mus musculus with 120 samples.

How the data were processed

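Left kidneys of C57BL/6 mice were profiled on 120 oligonucleotide arrays with 2 dyes, 60 after obstruction of the left ureter (UUO) and 60 after a sham operation. Per the labels, total RNA was taken with Trizol and 5 µg was labelled. The kidney sample was labelled with Cy5 and the Mouse Universal Reference, an RNA mixture of cell lines, with Cy3 on every array, with no dye swap. Samples were put in 21 groups by arm and time as the labels give them; the labels name no sex, slide or day, and slide and scan day were read from the scanner files, which held 30 slides and 9 scan days.

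The deposited scanner files were written by Agilent Feature Extraction version 10.7.3.1 and held 45018 spots, 1639 of them controls. Per the file headers, the background-subtracted and dye-normalized ratio is given as log10 of Cy5 over Cy3, and the mean and background signals are given as scanner intensity. Per the file headers, other columns hold flags of 0 or 1, for spots well above background and for outlier spots. The deposited series table holds log10 ratios in 44996 lines; 100% of its values equalled the scanner's log ratio within rounding to 3 digits, and its column medians ranged from -0.0857 to 0. Some gene names in the scanner file of UUO 1 h replicate 7 read as dates, so that names were taken from another array of the same design.

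Probe annotation was brought up to date with the reference table of accessions and symbols: of 41174 probes, 23374 were named by accession, 6724 by symbol, 2908 by a synonym and 1845 by the name in the file, and 6323 had no gene name. Coordinates are those in the files, on mouse build mm8; no genome sequence was at hand. Mean signals were background-corrected with normexp (offset 50) and normalized within arrays by loess in limma version 3.58.1 under R 4.3.3. Outlier spots were excluded. A probe was used if it was well above background in Cy5 on at least 4 arrays of some group and had at least 2 values in each group, and a gene was represented by its brightest probe, which gave 17685 genes. 

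A linear model with 21 group means was fitted with limma, and contrasts were tested with moderated t statistics and the Benjamini-Hochberg adjustment, with a threshold of 0.05. The contrasts were UUO against sham at each of the 10 times, their mean, the difference of the UUO effect between 4 late times (1 d to 7 d) and 6 early times (0.5 h to 12 h), the differences between neighbouring stages, and sham kidneys against sham kidneys of 0 h. Sham arrays serve as the shared control of several contrasts. Fold changes are given as log2 with the model's standard error, which takes a gene's spread as the same in all 21 groups. The p-values measure the spread between these arrays, part of which may be technical. The prior of the variance model had 2.36 degrees of freedom and a prior SD of 0.198; the median residual SD of a gene was 0.232.

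Lists of 37 processes and cell types, written before the data were examined, were tested with camera at its preset correlation of 0.01 and with the correlation estimated from the data, and with fry, a rotation test of whether a list moves in a direction. Members that passed are counted over all genes and adjusted over the list alone. The genes named in the text follow a rule made before the data were examined: 20 fixed marker genes, up to 5 of the largest increases and decreases of each comparison whose arrays did not overlap, and up to 4 members with the largest change of each list. Where a probe was well above background on no array of a single group of a same-time comparison, its fold is given as a lower bound from the Cy5 channel, and is left out where that bound exceeded the fold of the log ratios. Where the probe was well above background on only some arrays of a group, the fold of the log ratios is given with their number. Among the genes that this rule allows, the examples in the text were picked after the alternatives had been run, and genes whose direction turned under an alternative, whose call was lost without a single array or whose probes gave opposite calls were mostly passed over, so that the examples are steadier than the lists they come from.

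The alternatives were array weights, the series table, the scanner's log ratio, no background subtraction, quantile normalization of the average intensity of both dyes between arrays (which left the log ratios as they were), median centring, Cy5 alone with quantile normalization, no filter, a strict filter, outlier spots kept, a mean over probes, a trended and robust prior, slide or scan day as a block, a replicate block, each array left out in turn, and arrays of a single time. After the data were seen, a fit without the scan day of weak signal and a term for Y-linked RNA were added. For each contrast, 100 splits of the arrays were fitted. On simulated data with 200 changed genes of 17685 the method was tested at 3 sizes: at log2 1, 83.6% of changed genes were recovered at 5 h, 86.6% at 1 d, 88.1% at 7 d, 100% for the mean over times, 92.5% for late minus early and 95.5% for early sham against 0 h, with 6, 9, 10, 11, 13 and 9 calls among unchanged genes. The simulated noise was independent between genes and alike on every array, with no scan day and no weak arrays. These numbers therefore do not give the share of false calls on the real arrays.

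Other tools were the R packages jsonlite 2.0.0 and statmod 1.5.0, the package for tables, data.table, in version 1.17.8, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The deposited replicate numbers were checked as pairs of UUO and sham: 60 numbers were shared, 36 of them at the same time, and the median correlation of deviations was 0.13, so that they were not treated as pairs. Probes without a gene name were left out of the main tests. No array was left out.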

Results

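RNA of the left kidney of C57BL/6 mice was measured after unilateral ureteral obstruction (UUO), in which the left ureter was tied, or after a sham operation, in which the ureter was freed and left open. Obstruction is a standard way to bring on tubular injury and fibrosis in a rodent kidney. The UUO arm had 6 arrays at each of 10 times, 0.5 h, 1 h, 3 h, 5 h, 7 h, 12 h, 1 d, 3 d, 5 d and 7 d. The sham arm had 4 arrays at 0 h, 5 arrays at 1 h, 3 h, 5 d and 7 d, and 6 arrays at each of the other times, so that the series held 120 arrays in 21 groups. Each array compared a kidney (Cy5 dye) with a common reference RNA from mouse cell lines (Cy3 dye).

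The kidney channel stood well above background for 58.9% to 78.5% of probes on 104 arrays. On the other 16 arrays, all scanned on a single day, the share was 17.2% to 42.0%. Those 16 arrays comprised 2 UUO and 2 sham arrays of 5 h, 2 UUO and 4 sham arrays of 12 h, and 4 UUO and 2 sham arrays of 1 d. The number of arrays limits the precision: a same-time fold change had a median standard error of 0.14 on the log2 scale over 17685 genes. RNA of Y-linked genes was present on 63 of the 120 arrays and spread unevenly over the groups, from 1 of 6 sham arrays at 0.5 h to all 5 sham arrays at 3 h. The labels give no sex for the mice. Probe positions in the array files refer to mouse build mm8: the Spp1 probe lies on chromosome 5 from 104681071 to 104681130, and the Egf probe on chromosome 3 from 129669930 to 129669989.

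**Figure D1:**
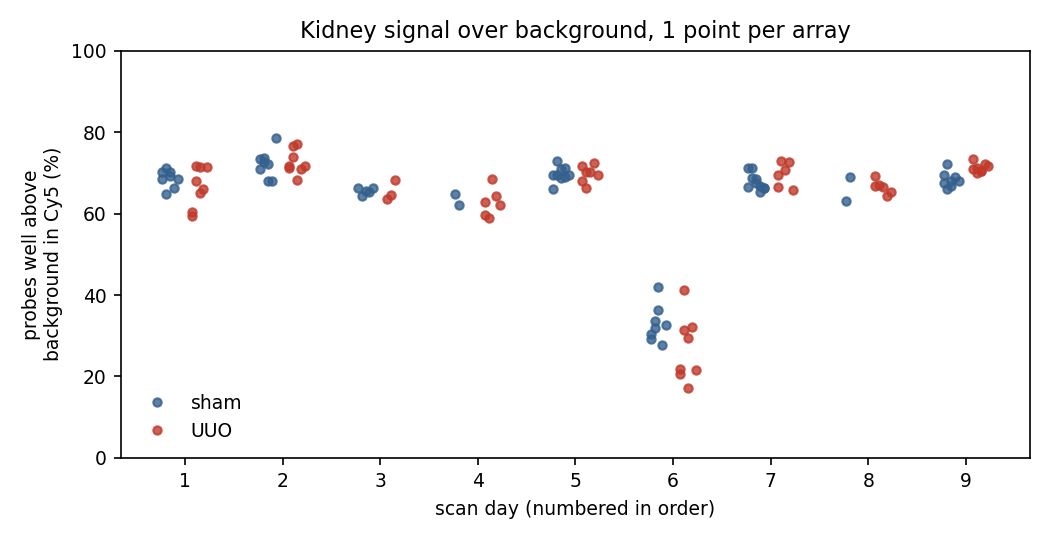
Percentage of probes well above background in the kidney (Cy5) channel, vertical axis, by scan day in running order, horizontal axis, with 1 point per array coloured by arm. The 16 arrays of scan day 6 lie between 17.2% and 42.0%, and the arrays of the other 8 scan days between 58.9% and 78.5%.

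The first question was which kidney genes differ between UUO and sham within 3 h of the operation. No single gene passed the test at 0.5 h, 1 h or 3 h. The immediate early response genes are switched on within minutes by many stimuli, and many of them encode transcription factors. These genes stood apart as a group. At 1 h 5 of their 17 measured members were higher in UUO when adjusted over the list alone and none over all genes, and the list median was 0.42 (camera adjusted p = 1.19e-13, adjusted p = 0.0278 with an estimated correlation). At 3 h 3 members passed over the list alone, and the list median was 0.45 (camera adjusted p = 6.49e-20, adjusted p = 0.00425 with an estimated correlation). Atf3, a stress-induced transcription factor of this list, measured 1.10 ± 0.24 (SE, 6 UUO and 5 sham arrays) at 3 h with adjusted p = 0.312, and 5 of 6 UUO arrays lay above all sham arrays. With the slide as a block Atf3 passed (1.29, adjusted p = 0.0335). At 0.5 h the list median was 0.15, or -0.21 under median centring, with camera adjusted p = 0.00653 (adjusted p = 0.619 with an estimated correlation). The neutrophil list, with 7 of 12 members measured, had a median of 0.23 at 1 h (camera adjusted p = 0.000487, adjusted p = 0.0484 with an estimated correlation).

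By limma the count of changed genes was 0 at each of these times, while 1137 genes at 0.5 h, 371 at 1 h and about 2.1e+02 at 3 h had an unadjusted p under 0.05. With array weights the counts were 504, 1 and 6. Without UUO 0.5 h replicate 6 the count at 0.5 h was 255. The counts with the scan day as a block were 0 at each time, and with the slide as a block 0, 0 and 1.

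At 5 h 27 genes were higher and 1 was lower in UUO than in sham. Median centring gave 0 genes, and so did the arrays of that time fitted alone. Each call named here ended in both. Egr1, an immediate early transcription factor, rose by 2.64 ± 0.37 on the log2 scale (SE, n = 6 arrays per arm, 6.25-fold, adjusted p = 5.96e-07). Atf3 rose by 2.15 ± 0.23 (adjusted p = 7.02e-11) and Btg2, which restrains cell proliferation, by 1.29 ± 0.18 (adjusted p = 3.26e-07). For these 3 genes all 6 UUO arrays lay above all 6 sham arrays. Nr4a1, an orphan nuclear receptor of the same list, rose by 1.73 ± 0.31 with 5 of 6 arrays above every sham array (adjusted p = 0.000314). Gdf15, a stress cytokine placed in the p53 target list, rose by 1.41 ± 0.22 with 4 of 6 (adjusted p = 1.74e-05). Zfp61, a zinc finger protein, was the gene that fell, by 0.45 ± 0.10 (adjusted p = 0.0236, 6 of 6 arrays below every sham array). The Atf3 probe stood well above background on 5 of 6 sham arrays and the Zfp61 probe on 5 of 6 UUO arrays.

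Of the 17 immediate early genes 10 rose at 5 h and 14 did when adjusted over the list alone, with a list median of 0.98 (camera adjusted p = 7.21e-71, adjusted p = 3.34e-08 with an estimated correlation). Among 15 genes for chemokines and NF-kB targets, the inflammatory signals that call in white blood cells, none passed over all genes and 6 did over the list alone (median 0.46, camera adjusted p = 7.36e-15, adjusted p = 0.00205 with an estimated correlation). The scan day as a block gave 29 changed genes, 23 of them among the 28, and the 28 genes kept their sign within each of the 2 scan days that held both arms. As the 28 genes had been picked on these same arrays, the shared sign is no independent support. Leaving out sham replicate 25 gave 10 changed genes, UUO replicate 21 gave 13 and UUO replicate 19 gave 18; leaving out UUO replicate 20 gave 43. The call of Zfp61 was lost without any of UUO replicates 21, 23 and 24 and sham replicates 21, 24, 25 and 26.

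At 7 h 378 genes rose and 290 fell. Egr1 was 14.8-fold higher (3.89 ± 0.39, SE, 6 UUO and 5 sham arrays with a value, adjusted p = 1.89e-13) and Atf3 9.50-fold higher (3.25 ± 0.23, n = 6 per arm, adjusted p = 4.37e-21). Ch25h, which makes 25-hydroxycholesterol, rose by 3.19 ± 0.39 (adjusted p = 8.31e-10) and Ccn1, a secreted matrix protein, by 3.05 ± 0.23 (adjusted p = 3.49e-20). Fos, a subunit of the AP-1 transcription factor, rose by 2.98 ± 0.47 (adjusted p = 1.54e-06, probe well above background on 5 of 6 sham arrays). Each of these 5 genes was above every sham array on 6 of 6 UUO arrays. Among the genes that fell were Fam167b (-1.04 ± 0.19, adjusted p = 6.24e-05), Rab19, a small GTPase (-1.02 ± 0.14, adjusted p = 3.02e-08), and Bmf, which promotes apoptosis (-0.93 ± 0.23, adjusted p = 0.00774), each below every sham array on 6 of 6 arrays.

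The immediate early list had 13 of 17 members up at 7 h (15 adjusted over the list alone, median 1.55, camera adjusted p = 1.55e-63, adjusted p = 1.18e-07 with an estimated correlation). Of 15 chemokine and NF-kB genes 11 rose (12 over the list alone, camera adjusted p = 2.41e-24, adjusted p = 4.19e-05 with an estimated correlation). Il6, the interleukin that drives the acute phase response, was at least 6.03-fold higher; the bound is from the Cy5 channel, stays open to dye bias and counts sham arrays on which the probe was not well above background at the level where it would be. Cxcl1, a neutrophil attractant, rose by 2.59 ± 0.37 and Ccl2, a monocyte attractant, by 1.09 ± 0.25 (adjusted p = 0.00217). Of 15 tubular injury genes 7 rose (8 over the list alone, camera adjusted p = 2.15e-10, adjusted p = 0.003 with an estimated correlation), among them Tnfrsf12a, the receptor for the cytokine TWEAK, by 2.24 ± 0.24. Of 12 measured NRF2 targets, the antioxidant enzymes, 3 rose (5 over the list alone, camera adjusted p = 9.51e-07, adjusted p = 0.00365 with an estimated correlation), among them Hmox1, heme oxygenase, by 1.70 ± 0.22. In the neutrophil list 4 of 7 measured members rose (camera adjusted p = 2.29e-08, adjusted p = 0.000588 with an estimated correlation). A fit with the scan day as a block called 816 genes, and median centring gave 19. These 19 were all higher in UUO, so that Fam167b, Rab19 and Bmf lost their calls under it. The excess of increases turned with no background subtraction (480 up, 533 down) and with array weights (770 up, 1046 down).

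The 12 h comparison had 786 genes up and 1376 down. Fgg, a chain of the clotting protein fibrinogen, rose by 5.85 ± 0.69 on the log2 scale (57.5-fold, SE, n = 6 per arm, adjusted p = 1.01e-10, 5 of 6 UUO arrays above every sham array), and Fga, another chain, by 4.08 ± 0.49 (adjusted p = 1.81e-10, 6 of 6). The Fgg values spread more in sham (SD 2.90) than in UUO (SD 0.72), which the shared spread of the model leaves out. Mt2, a metal-binding stress protein, rose by 3.66 ± 0.35 (adjusted p = 9.82e-15) and Plin2, which coats lipid droplets, by 3.40 ± 0.33 (adjusted p = 2.3e-14, 5 of 5 UUO arrays with a value). Lcn2, the kidney injury marker NGAL, rose by 2.77 ± 0.30 (adjusted p = 8.03e-12) and Spp1, the secreted phosphoprotein osteopontin, by 2.66 ± 0.35 (adjusted p = 5.15e-09). Slc4a1, the anion exchanger of intercalated cells, fell by 2.48 ± 0.51 (adjusted p = 0.000152), Aqp2, the vasopressin-regulated water channel, by 2.08 ± 0.31 (adjusted p = 1.77e-07), and Rhcg, an ammonia transporter of the collecting duct, by 2.01 ± 0.33 (adjusted p = 1.75e-06). Mt2, Lcn2, Spp1, Slc4a1, Aqp2 and Rhcg lay beyond every sham array on 6 of 6 UUO arrays. Probes stood well above background on 2 of 6 sham arrays for Lcn2, on 3 of 6 for Fga and on 5 of 6 UUO arrays for Slc4a1, so that part of these fold changes rests on values near background.

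Of 14 acute phase genes, which encode plasma proteins made in inflammation, 9 rose at 12 h (11 over the list alone, median 1.47, camera adjusted p = 9.81e-17, adjusted p = 7.78e-05 with an estimated correlation). Of the 15 tubular injury genes 9 rose (11 over the list alone, camera adjusted p = 4.59e-16, adjusted p = 0.000113 with an estimated correlation). Of the NRF2 targets 6 of 12 rose (7 over the list alone, camera adjusted p = 5.88e-11, adjusted p = 8.4e-05 with an estimated correlation), with Hmox1 at 2.52 ± 0.22 and Srxn1, which repairs peroxiredoxins, at 1.23 ± 0.14. The glucocorticoid and surgical stress list had 7 of 11 measured members up and 1 down (camera adjusted p = 1.88e-08, adjusted p = 0.053 with an estimated correlation). Of 10 thick ascending limb genes 4 fell (5 over the list alone, camera adjusted p = 0.00244, adjusted p = 0.446 with an estimated correlation). Of 16 oxidative phosphorylation genes 8 fell, with a list median of -0.35 that turned to 1.07 under median centring (camera adjusted p = 0.000272, adjusted p = 0.474 with an estimated correlation). Of 18 extracellular matrix genes 6 fell and 1 rose, with a list median of -0.66 that turned to 0.24 under median centring (camera adjusted p = 0.00711, adjusted p = 0.684 with an estimated correlation). The excess of decreases turned under the scanner's log ratio (52% up) and under median centring (87% up). The block by scan day gave 2415 genes. Of the 2162 genes, 99.3% and 95.7% kept their sign within the 2 scan days that held both arms. The genes had been picked on these same arrays, so that the shared sign is no independent support.

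At 1 d 2644 genes rose and 3568 fell, on arrays of which 4 of 6 UUO and 2 of 6 sham came from the scan day of weak signal. Fgg was 110-fold higher in UUO (6.78 ± 0.69, SE, n = 6 per arm, adjusted p = 1.14e-13) and Spp1 35.9-fold higher (5.17 ± 0.35, adjusted p = 1.29e-22). Krt20, a keratin found in injured tubules, rose by 3.79 ± 0.47 (adjusted p = 3.21e-10), and Saa2, serum amyloid A, by 3.47 ± 0.41 (adjusted p = 5.99e-11). Egf, the growth factor made by distal tubules, fell by 4.84 ± 0.36 (28.7-fold, adjusted p = 5.58e-21), Slc12a1, the sodium-potassium-chloride cotransporter of the thick ascending limb, by 5.07 ± 0.56 (adjusted p = 4.15e-12), and Wfdc15b, a protease inhibitor, by 4.63 ± 0.45 (adjusted p = 1.33e-14). All 7 genes lay beyond every sham array on 6 of 6 UUO arrays. The Saa2 probe stood well above background on 1 of 6 sham arrays and the Egf probe on 5 of 6 UUO arrays.

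At 1 d all 9 principal cell genes of the collecting duct fell (median -2.60, camera adjusted p = 7.36e-07, adjusted p = 0.21 with an estimated correlation). So did all 9 intercalated cell genes (median -1.64, camera adjusted p = 4.3e-05, adjusted p = 0.363 with an estimated correlation). Of 10 thick ascending limb genes 8 fell (9 over the list alone, camera adjusted p = 4.75e-07, adjusted p = 0.1 with an estimated correlation). Of 9 distal convoluted and connecting tubule genes 7 fell (camera adjusted p = 2.43e-05, adjusted p = 0.149 with an estimated correlation). Aqp2 fell by 2.82 ± 0.31, Aqp3, the glycerol and water channel beside it, by 3.27 ± 0.41, and Calb1, the calcium-binding calbindin, by 4.02 ± 0.47. Of 15 proximal tubule genes 9 fell (median -0.88, or 0.82 by the scanner software's log ratio, camera adjusted p = 0.0152, adjusted p = 0.635 with an estimated correlation). Of 12 endothelial genes 11 fell, among them Plvap, a protein of capillary pores, by 2.79 ± 0.42 (camera adjusted p = 6.49e-06, adjusted p = 0.394 with an estimated correlation). Of 10 podocyte genes 6 fell, among them Podxl, podocalyxin, by 1.69 ± 0.40 (camera adjusted p = 0.00361, adjusted p = 0.595 with an estimated correlation). Umod, the urinary protein uromodulin, measured 0.59 ± 0.54 with adjusted p = 0.402. Probes stood well above background on 5 of 6 UUO arrays for Aqp2 and Plvap and on 3 of 6 for Podxl. Scan day 6 was that of weak signal (4 UUO and 2 sham arrays), and scan day 7 held 1 UUO and 4 sham arrays. Within these days the list medians were -1.95 and -1.29 for principal cells, and -0.42 and -1.06 for intercalated cells. They were -2.54 and -0.95 for the thick ascending limb and -1.86 and -0.85 for the distal convoluted and connecting tubule. For proximal tubule, endothelial and podocyte genes they were -1.54 and -0.11, -1.03 and -0.88, and -0.25 and -0.73.

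Of 15 tubular injury genes 12 rose at 1 d, with a list median of 1.35 that turned to -0.22 under median centring (camera adjusted p = 3.19e-14, adjusted p = 0.000317 with an estimated correlation). Of 14 acute phase genes 9 rose (median 1.80, camera adjusted p = 2.33e-09, adjusted p = 0.00435 with an estimated correlation). All 14 DNA replication genes rose, with a median of 1.04 that turned to -0.59 under median centring (camera adjusted p = 4.83e-10, adjusted p = 0.197 with an estimated correlation); Uhrf1, which keeps DNA methylation through replication, rose by 2.26 ± 0.41. Of 15 mitotic cell cycle genes 14 rose, with a median of 1.15 that turned to -0.37 under median centring (camera adjusted p = 1.69e-05, adjusted p = 0.539 with an estimated correlation). When scan day was a block, 13 DNA replication genes and 0 mitotic genes passed at 1 d.

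The count at 1 d was 3433 with the scan day as a block, 1481 with the slide as a block and 2932 without the 16 weak arrays. Over all genes called at 1 d, the median log2 fold change with the scan day as a block was 64.4% of its size without it. The excess of decreases turned with the slide as a block (754 up, 727 down) and grew under median centring (868 up, 6086 down). No slide held both arms at 1 d; the call of Egf was kept with the slide as a block (-2.78), while Slc12a1 (-2.08, adjusted p = 0.137), Calb1 (-0.65, adjusted p = 0.698), Aqp2 (-0.97, adjusted p = 0.294), Aqp3 (-1.40, adjusted p = 0.277), Plvap (-1.0, adjusted p = 0.444) and Wfdc15b (-0.83, adjusted p = 0.519) lost theirs.

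At 3 d 1978 genes rose and 1724 fell. C3, the central complement protein, was 45.2-fold higher (5.50 ± 0.40, SE, n = 6 per arm, adjusted p = 1.7e-21), Spp1 21.7-fold higher (4.44 ± 0.35) and Krt20 20.7-fold higher (4.37 ± 0.47). Vcam1, an adhesion molecule for white blood cells, rose by 3.91 ± 0.28 (adjusted p = 2.72e-21) and Col1a1, a chain of fibrillar collagen, by 2.59 ± 0.32 (adjusted p = 1.6e-10). Egf fell by 2.95 ± 0.36 (adjusted p = 7.72e-11), Pgam2, a glycolytic enzyme, by 2.30 ± 0.22 (adjusted p = 7.27e-15), and Lpl, lipoprotein lipase, by 2.13 ± 0.46 (adjusted p = 0.000187). Each named gene lay beyond every sham array on 6 of 6 UUO arrays.

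All 15 tubular injury genes rose at 3 d (median 1.86, camera adjusted p = 2.61e-20, adjusted p = 1.14e-05 with an estimated correlation). Of 13 macrophage genes 11 rose (12 over the list alone, median 1.42, camera adjusted p = 1.02e-15, adjusted p = 0.000891 with an estimated correlation), among them Lyz2, lysozyme, by 2.52 ± 0.26, Trem2, a lipid receptor, by 2.80 ± 0.38, and Ctss, a lysosomal protease, by 2.43 ± 0.28. Of 15 chemokine and NF-kB genes 12 rose (camera adjusted p = 4.95e-14, adjusted p = 0.00299 with an estimated correlation), with Cxcl10, a T cell attractant, at 3.63 ± 0.28. All 16 oxidative phosphorylation genes fell (median -0.87, camera adjusted p = 4.35e-20, adjusted p = 0.00623 with an estimated correlation), among them Sdhb, a subunit of succinate dehydrogenase, by 1.64 ± 0.26. Of 18 matrix genes 11 rose (median 0.92, camera adjusted p = 5.95e-08, adjusted p = 0.27 with an estimated correlation), with Timp1, an inhibitor of matrix proteases, at 3.29 ± 0.30. Blocking by scan day gave 3527 genes, blocking by slide 1505, and median centring 492.

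At 5 d 2574 genes rose and 2580 fell. C3 was 88.7-fold higher (6.47 ± 0.41, SE, 6 UUO and 5 sham arrays, adjusted p = 5.28e-25), Krt20 65.2-fold higher (6.03 ± 0.50, adjusted p = 8.57e-19) and Vcam1 28.2-fold higher (4.82 ± 0.30, adjusted p = 1.44e-25). Sprr2f, a protein of stressed epithelium, rose by 4.60 ± 0.53 (adjusted p = 4.05e-12, probe well above background on 3 of 5 sham arrays). Ces1g, a carboxylesterase, fell by 3.69 ± 0.75 (adjusted p = 3.84e-05), Kcnt1, a potassium channel, by 3.43 ± 0.61 (adjusted p = 2.92e-06), and Slc4a1 by 2.68 ± 0.53 (adjusted p = 2.5e-05). Pvalb, the calcium-binding parvalbumin of the distal convoluted tubule, was at least 11.1-fold lower, with no UUO array on which its probe stood well above background. Every gene named here lay beyond all 5 sham arrays on 6 of 6 UUO arrays.

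All 13 macrophage genes rose at 5 d (median 2.77, camera adjusted p = 3.6e-21, adjusted p = 7.98e-05 with an estimated correlation). Of 15 tubular injury genes 14 rose (median 2.04, camera adjusted p = 1.52e-20, adjusted p = 1.14e-05 with an estimated correlation). Of 13 TGF-beta pathway genes, the main profibrotic signal, 9 rose (11 over the list alone, camera adjusted p = 6.17e-06, adjusted p = 0.0145 with an estimated correlation), with Tgfbi, a secreted matrix protein, at 2.48 ± 0.29. All 16 oxidative phosphorylation genes fell (median -1.05, camera adjusted p = 1.37e-17, adjusted p = 0.0126 with an estimated correlation). Of 16 fatty acid oxidation genes 10 fell (13 over the list alone, camera adjusted p = 4.95e-06, adjusted p = 0.238 with an estimated correlation), among them Acaa2, a thiolase, by 1.79 ± 0.21. Of 13 complement genes 9 rose (camera adjusted p = 8.39e-06, adjusted p = 0.053 with an estimated correlation). Blocking by scan day gave 6435 genes, and median centring 1313, of which 88.7% were up.

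At 7 d 3343 genes rose and 4141 fell. Col1a1 was 17.5-fold higher (4.13 ± 0.33, SE, 6 UUO and 5 sham arrays, adjusted p = 1.57e-19) and Col3a1, the collagen that accompanies it, 14.2-fold higher (3.83 ± 0.34, adjusted p = 1.71e-17). C3 rose by 5.25 ± 0.41 (adjusted p = 3.9e-20), Vcam1 by 5.08 ± 0.30 (adjusted p = 1.37e-27) and Lgi2, a secreted protein, by 5.10 ± 0.39 (adjusted p = 4.52e-21). Slc6a19, the neutral amino acid transporter of the proximal tubule, fell by 3.44 ± 0.85 (adjusted p = 0.000474), Kcnt1 by 3.54 ± 0.61 (adjusted p = 9.06e-07) and Egf by 2.71 ± 0.37 (adjusted p = 1.81e-09). Each was beyond all 5 sham arrays on 6 of 6 UUO arrays.

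Of 18 matrix genes 17 rose at 7 d (18 over the list alone, median 2.02, camera adjusted p = 1.36e-13, adjusted p = 0.0923 with an estimated correlation). Of 12 fibroblast and mural cell genes 10 rose (11 over the list alone, camera adjusted p = 6.58e-07, adjusted p = 0.0588 with an estimated correlation), with Lum, the proteoglycan lumican, at 3.19 ± 0.42 and Acta2, smooth muscle actin, at 1.42 ± 0.22. All 13 macrophage genes rose (median 2.81, camera adjusted p = 6.58e-18, adjusted p = 0.000317 with an estimated correlation), with Ctss at 4.08 ± 0.29. Of 13 TGF-beta pathway genes 12 rose (camera adjusted p = 2.94e-07, adjusted p = 0.00435 with an estimated correlation), with Tgfb1 itself at 1.24 ± 0.15. Of 15 interferon response genes 12 rose (14 over the list alone, camera adjusted p = 6.8e-07, adjusted p = 0.175 with an estimated correlation), with Oasl2, an antiviral enzyme, at 2.00 ± 0.23. All 16 oxidative phosphorylation genes fell (median -1.26, camera adjusted p = 4.99e-17, adjusted p = 0.0145 with an estimated correlation). Of 16 fatty acid oxidation genes 15 fell (camera adjusted p = 2.11e-07, adjusted p = 0.157 with an estimated correlation), with Acadm, a medium-chain dehydrogenase, at -2.11 ± 0.26. Havcr1, the injury marker KIM-1, measured 0.91 ± 0.62 with adjusted p = 0.242. All 7 d arrays were scanned on the same day. The excess of decreases turned under median centring (1196 up, 795 down). The genes up at 5 d and at 7 d shared 2323 members against 486.6 for independent lists, and those down shared 2405 against 604.1; 757 genes were up and 998 down at each of 1 d, 3 d, 5 d and 7 d.

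Of 15 tubular injury genes 14 rose at 7 d (median 2.06, camera adjusted p = 1.22e-15, adjusted p = 0.000131 with an estimated correlation). So did 14 of 15 chemokine and NF-kB genes (median 1.60, camera adjusted p = 6.85e-11, adjusted p = 0.0111 with an estimated correlation). Of 17 immediate early genes 12 rose (camera adjusted p = 3.79e-06, adjusted p = 0.241 with an estimated correlation). Of 13 p53 targets 5 rose and 1 fell (camera adjusted p = 0.0693), with Cdkn1a, the p21 brake on the cell cycle, at 1.33 ± 0.32. Of 14 circadian clock genes 5 fell (camera adjusted p = 0.23), with Tef, a clock-driven transcription factor, at -1.58 ± 0.30. Of 15 hypoxia and glycolysis genes 2 rose and 6 fell (camera adjusted p = 0.361), of the heat shock genes 1 rose and 4 fell (camera adjusted p = 0.484), and of 13 endoplasmic reticulum stress genes 2 rose and 1 fell (camera adjusted p = 0.914). Among lists of cell types, 5 of 8 urothelium genes rose (camera adjusted p = 0.00394, adjusted p = 0.438 with an estimated correlation), with Krt14, a keratin of basal epithelium, at 2.45 ± 0.17. Of 7 B cell genes 4 rose (camera adjusted p = 0.092), and of the T and natural killer cell genes 5 rose and 2 fell (camera adjusted p = 0.316). Of 9 adipocyte genes 2 fell (camera adjusted p = 0.478) and of 8 skeletal muscle genes 1 rose (camera adjusted p = 0.716). None passed among the adrenal genes (median 0.13), the erythroid genes (median -0.63) or the sex-linked genes (median -0.57).

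**Figure D2:**
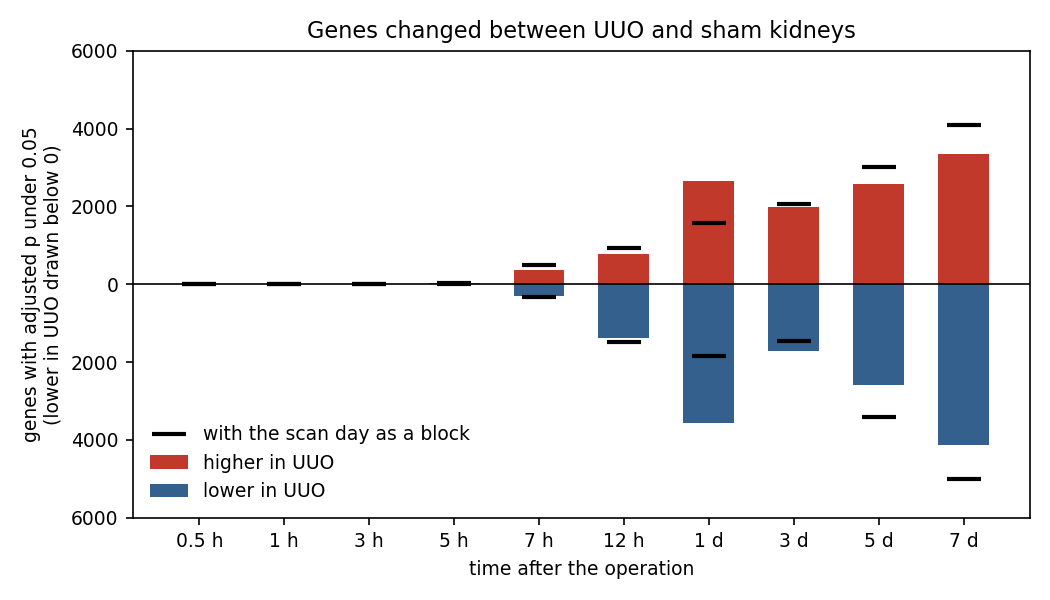
Number of genes with adjusted p under 0.05 between UUO and sham, vertical axis, by time after the operation, horizontal axis, with genes higher in UUO above 0 and genes lower in UUO drawn below it; black marks give the same counts with the scan day as a block. The counts run from 0 at 0.5 h, 1 h and 3 h through 27 up and 1 down at 5 h to 3343 up and 4141 down at 7 d, with 2644 up and 3568 down at 1 d, where the block gave 1582 up and 1851 down.

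**Figure D3:**
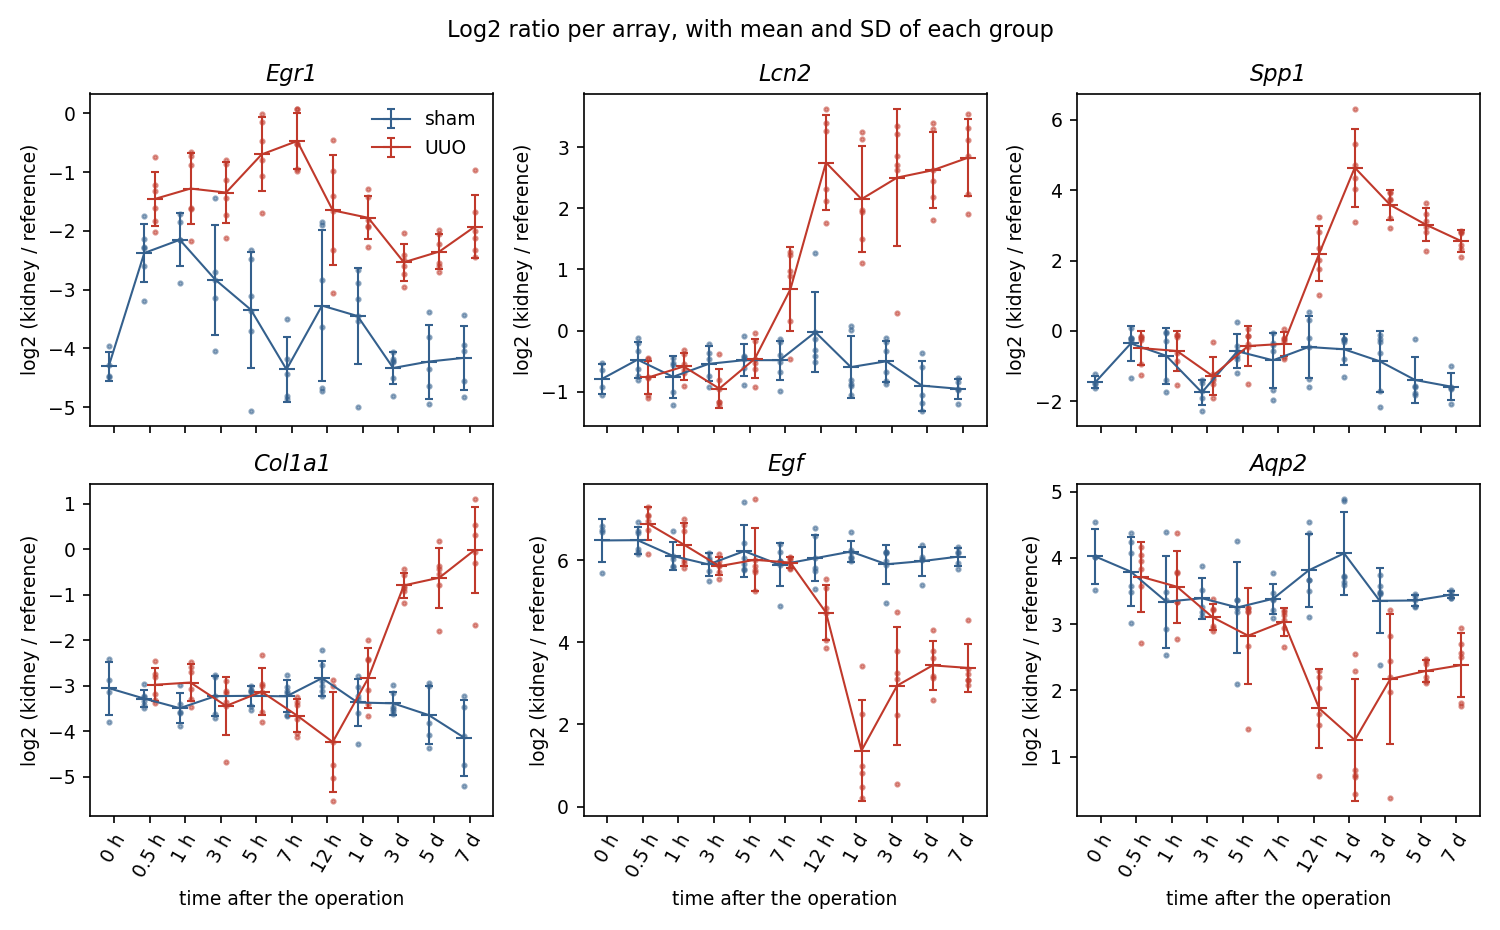
Log2 ratio of kidney over reference for Egr1, Lcn2, Spp1, Col1a1, Egf and Aqp2, vertical axes, by time after the operation as evenly spaced categories, horizontal axes, with 1 point per array and the mean and SD of each group (4 to 6 arrays) as lines and bars. Spp1 had a mean of 4.64 in UUO and -0.52 in sham at 1 d, and Egf one of 1.37 and 6.21.

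**Figure D4:**
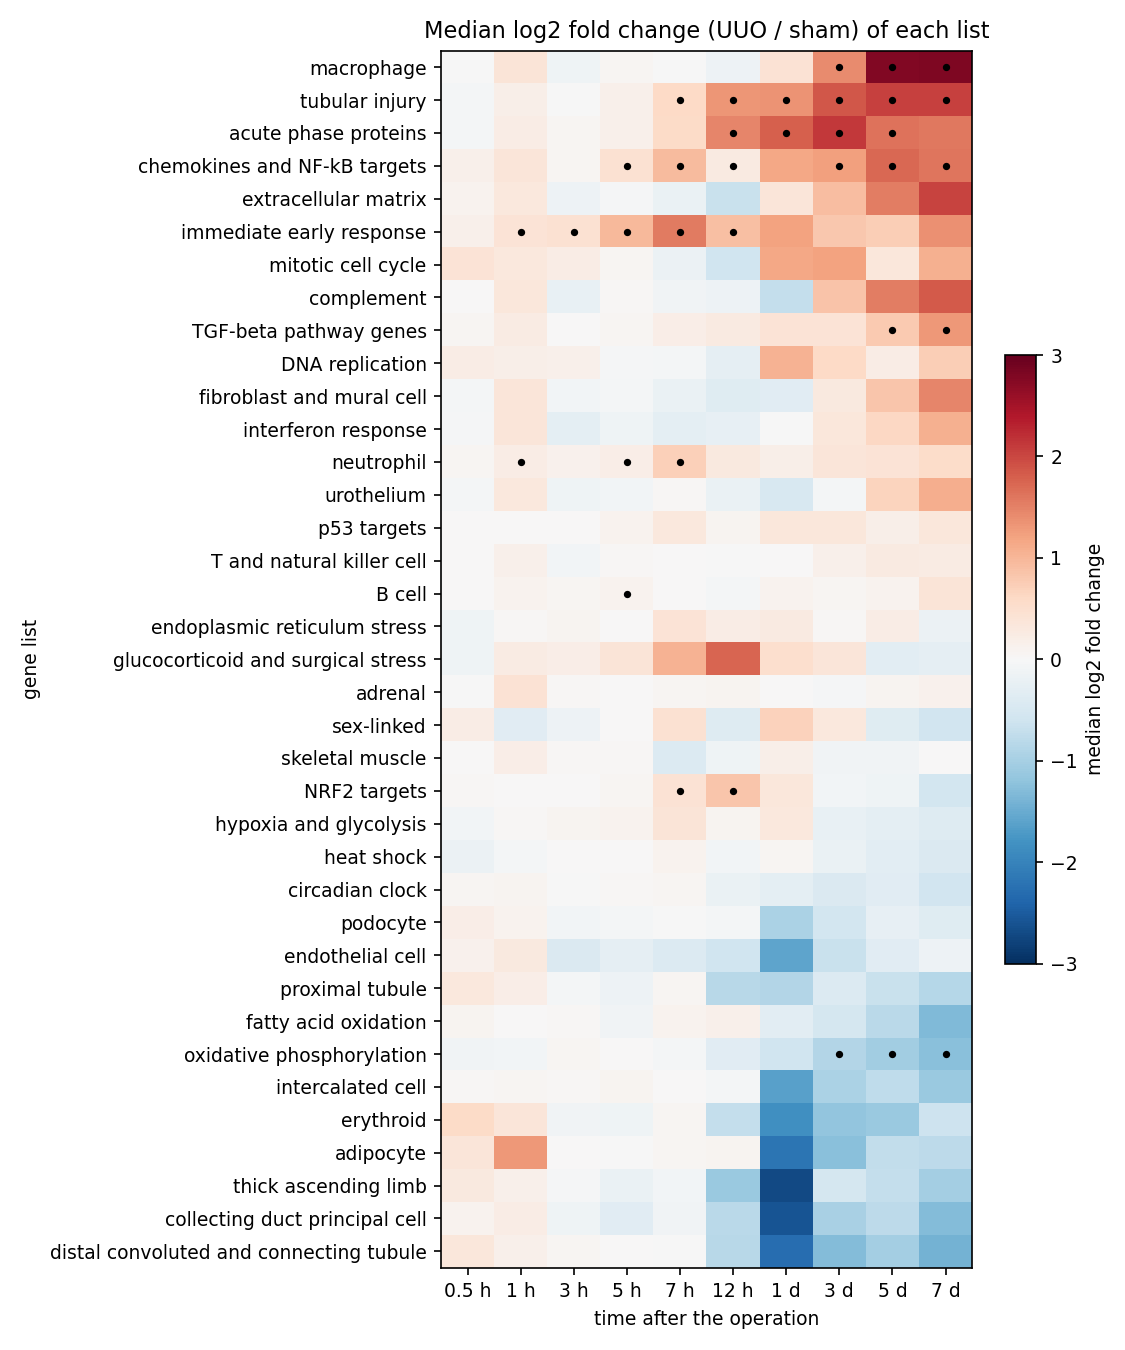
Median log2 fold change (UUO over sham) of the measured members of each of 37 gene lists, colour scale, by list, vertical axis, and time after the operation, horizontal axis; a dot marks a camera adjusted p under 0.05 with an estimated correlation. The tubular injury median was 2.06 and the oxidative phosphorylation median -1.26 at 7 d; 35 of the 237 list directions that camera called with its preset correlation over all 17 comparisons turned under median centring.

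Over the mean of the 10 same-time differences, the comparison that the series design names, 3551 genes were higher and 4523 lower in UUO. Krt20 rose by 2.49 ± 0.15 on the log2 scale (SE, 116 arrays, adjusted p = 1.81e-27), Spp1 by 2.19 ± 0.11 (adjusted p = 1.36e-32) and Klf6, a zinc finger transcription factor of the immediate early list, by 1.42 ± 0.06 (adjusted p = 2.4e-37). Egf fell by 1.39 ± 0.11 (adjusted p = 1.87e-19) and Slc4a1 by 1.37 ± 0.16 (adjusted p = 7.36e-12, probe well above background on 2 of 6 UUO arrays at 1 d). All 15 tubular injury genes rose (camera adjusted p = 7.64e-21, adjusted p = 1.14e-05 with an estimated correlation), 16 of 17 immediate early genes rose (camera adjusted p = 1.21e-19, adjusted p = 0.00435 with an estimated correlation) and 14 of 15 chemokine and NF-kB genes rose (camera adjusted p = 3.54e-18, adjusted p = 0.000443 with an estimated correlation). Of the fixed marker genes, Umod measured -0.04 ± 0.17 with adjusted p = 0.879. The count was 8907 when scan day was a block and 2170 under median centring.

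Whether the UUO effect itself differed between the late times (1 d to 7 d) and the early ones (0.5 h to 12 h) was tested as an interaction, which called 3916 genes with a more positive and 4502 with a more negative late effect. The late effect exceeded the early one by 4.70 ± 0.26 for C3 (SE, 116 arrays, adjusted p = 6.07e-30), by 3.91 ± 0.23 for Spp1 (adjusted p = 6.16e-28) and by 3.58 ± 0.19 for Vcam1 (adjusted p = 1.32e-31). It was lower by 4.24 ± 0.81 for Cidea, a lipid droplet protein of brown fat (log2 difference -4.24, adjusted p = 6.32e-06), and the difference was -3.31 ± 0.38 for Kcnt1 (adjusted p = 2.97e-12), whose probe stood well above background on 2 of 6 UUO arrays at 1 d. The late effect was higher for 12 of 13 macrophage genes (13 over the list alone, camera adjusted p = 1.55e-16, adjusted p = 0.000588 with an estimated correlation) and 16 of 18 matrix genes (18 over the list alone, camera adjusted p = 2.75e-12, adjusted p = 0.116 with an estimated correlation). It was lower for all 16 oxidative phosphorylation genes (camera adjusted p = 2.16e-16, adjusted p = 0.018 with an estimated correlation) and for all 9 intercalated cell genes (camera adjusted p = 0.000866, adjusted p = 0.527 with an estimated correlation). The count was 7632 when scan day was a block, which ended the excess of more negative effects (3821 up, 3811 down). With the slide as a block it was 5211 and under median centring 2422. The excess of more negative effects turned in both (2855 up and 2356 down, 1311 up and 1111 down).

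Between 12 h and 1 d the UUO effect rose for 1126 genes and fell for 490. This majority turned under the scanner's log ratio (871 up, 2030 down), Cy5 alone (533 up, 1100 down), median centring (1938 up, 10036 down) and array weights (5347 up, 6848 down). Egf dropped further by 3.52 ± 0.50 (log2 difference -3.52, SE, n = 6 per group, adjusted p = 5.11e-06), and Hspa1a, the inducible heat shock protein, differed by -2.60 ± 0.53 (adjusted p = 0.00174). Exo1, an exonuclease of DNA repair, differed by 2.53 ± 0.64 (adjusted p = 0.00881) and Dtl, an adaptor of a ubiquitin ligase in S phase, by 2.66 ± 0.71 (adjusted p = 0.0139); their probes stood well above background on 3 and 2 of 6 UUO arrays at 1 d. All 14 DNA replication genes had a more positive effect at 1 d, with a median of 1.31 that turned to -1.51 under median centring (camera adjusted p = 3.36e-13, adjusted p = 0.107 with an estimated correlation). With the scan day as a block 44 genes passed, 41 of them among the 1616 called without it, with Egf (-3.26, adjusted p = 0.000139) and with none of the DNA replication genes, while Exo1 (0.81, adjusted p = 0.409), Dtl (0.91, adjusted p = 0.497) and Hspa1a (-1.89, adjusted p = 0.0799) lost their calls. With the slide as a block 15 genes passed, and the call of Egf was lost (-0.95, adjusted p = 0.543). Without the 16 weak arrays the count was 94, and leaving out single arrays moved it by more than 1.5 times for 22 of 24 arrays. Among 1 d arrays, it was 535, 548 and 683 without UUO replicates 40, 37 and 38, 3419 and 4318 without UUO replicates 42 and 41, 622, 780, 782 and 918 without sham replicates 44, 41, 42 and 43, and 3285 and 3534 without sham replicates 40 and 39. Among 12 h arrays, it was 602, 636, 653 and 1040 without UUO replicates 33, 34, 31 and 32, 3258 and 3615 without UUO replicates 35 and 36, 534, 626 and 747 without sham replicates 36, 38 and 37, and 2965 and 3460 without sham replicates 33 and 35.

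Between 1 d and 3 d the effect rose for 210 genes and fell for 57. Ubd, a ubiquitin-like protein induced by cytokines, differed by 3.49 ± 0.40 (SE, n = 6 per group, adjusted p = 7.02e-10), Vcam1 by 2.85 ± 0.40 (adjusted p = 1.51e-06) and Slc12a1 by 3.41 ± 0.80 (adjusted p = 0.00895). In the complement list 2 of 13 genes passed (10 over the list alone, median 1.75, camera adjusted p = 1.2e-09, adjusted p = 0.00425 with an estimated correlation), and in the macrophage list 5 of 13 (9 over the list alone, camera adjusted p = 2.16e-10, adjusted p = 0.0109 with an estimated correlation), with Mrc1, the mannose receptor, at 2.64 ± 0.52 and Lyz2 at 2.22 ± 0.36. The probes of Ubd and Mrc1 stood well above background on 2 of 6 UUO arrays at 1 d. Blocking by scan day gave 320 genes, and blocking by slide ended the call of Slc12a1 (2.05, adjusted p = 0.296). The count was 868 without UUO 3 d replicate 46, 564 without UUO 1 d replicate 42, 462 without UUO 1 d replicate 41, 428 without sham 1 d replicate 39 and about 1.7e+02 without UUO 3 d replicate 43.

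Between 3 d and 7 d the effect differed for 510 genes and rose for 337 of them. Ccl8, a monocyte attractant, differed by 2.26 ± 0.34 (SE, 6 UUO arrays at each time, 6 sham arrays at 3 d and 5 at 7 d, adjusted p = 3.06e-06), Ms4a7, a macrophage membrane protein, by 2.24 ± 0.42 (adjusted p = 0.000412) and Lum by 2.66 ± 0.59 (adjusted p = 0.00365). Ahcy, which clears S-adenosylhomocysteine, differed by -1.30 ± 0.27 (adjusted p = 0.00154). In the fibroblast and mural cell list 5 of 12 genes passed (8 over the list alone, camera adjusted p = 5e-10, adjusted p = 0.012 with an estimated correlation), and in the macrophage list 5 of 13 (10 over the list alone, camera adjusted p = 2.29e-11, adjusted p = 0.00623 with an estimated correlation). Blocking by scan day gave 948 genes and blocking by slide 1398, without Lum (1.67, adjusted p = 0.0791). The slide block turned the majority (661 up, 737 down). The majority also turned under the strict filter (31.8% up of 314 genes) and with array weights (48.2% up). It stayed with the scan day as a block (62.9% up), and median centring gave 8 genes. Without UUO 7 d replicate 60 the count was about 2.3e+02, without UUO 3 d replicate 44 about 2.4e+02, without UUO 7 d replicate 59 it was 280, without sham 3 d replicate 49 it was 293, without sham 7 d replicate 56 it was 313, and without sham 7 d replicate 57 it was 324.

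The sham arm was compared with its own 0 h group, which asks what the operation alone does. In sham kidneys of 0.5 h to 12 h 566 genes were higher and 1110 lower than in the 4 kidneys of 0 h. Mt2 rose by 1.46 ± 0.32 (SE, 34 and 4 arrays, adjusted p = 0.00162), Ndrg1, a gene induced by stress and low oxygen, by 1.43 ± 0.27 (adjusted p = 0.000318), Errfi1, a brake on EGF receptor signalling, by 1.31 ± 0.27 (adjusted p = 0.000836) and Jun, a subunit of AP-1, by 0.99 ± 0.18 (adjusted p = 0.000227). Smcp, a protein known from sperm, fell by 2.75 ± 0.53 (adjusted p = 0.000407, probe well above background on 2 of 6 sham arrays at 12 h). Of 11 measured glucocorticoid and surgical stress genes 4 rose (6 over the list alone, median 1.03, camera adjusted p = 2.98e-07, adjusted p = 0.0834 with an estimated correlation). Of 17 immediate early genes 7 rose (10 over the list alone, camera adjusted p = 2.15e-08, adjusted p = 0.126 with an estimated correlation). All 4 arrays of 0 h carried Y-linked RNA, and several of the largest decreases were of genes higher on arrays with such RNA, such as Ugt2b37, a glucuronosyltransferase (-3.36 ± 1.00, adjusted p = 0.0196).

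In sham kidneys of 1 d to 7 d 741 genes were higher and 1363 lower than at 0 h. Under median centring 1274 were higher and 1074 lower. Ndrg1 was higher by 1.66 ± 0.28 (SE, 22 and 4 arrays, adjusted p = 1.85e-05), Grn, the lysosomal protein progranulin, by 1.51 ± 0.27 (adjusted p = 5.46e-05), and Smcp fell by 2.98 ± 0.55 (adjusted p = 7.91e-05). Over the 11 sham times 7843 genes changed by limma's moderated F test. The 0 h arrays came from 2 scan days, and with the scan day as a block the early comparison gave 94 genes, 76 of them among the 1676 called without it, with Mt2 at 2.10 (adjusted p = 0.00623), Ndrg1 at 1.65 (adjusted p = 0.00624) and Ugt2b37 at -2.62 (adjusted p = 0.373). Of the 94 genes 47 were higher and 47 lower, so that the excess of decreases was gone with this block. The late comparison then had 0 genes (1797 at an unadjusted p under 0.05), with Grn at 0.05 (adjusted p = 0.986), Ndrg1 at 1.63 (adjusted p = 0.259) and Smcp at -3.68 (adjusted p = 0.176). The test over all times then gave about 2.5e+02 genes. With the slide as a block the counts of the early, late and all-times tests were 0, 0 and 27. No sham array of 1 d to 7 d shared a scan day with the 0 h arrays, so that these arrays alone cannot tell time from scan day. Without sham 0 h replicate 1, 2 or 3 the early count was 425, 416 or 495 and without replicate 4 it was 2448, while the late count was 877, 936, 999 or 2781; the call of Ugt2b37 was lost without replicate 1, 2 or 3 in both comparisons.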

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

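Tests of the splits for all 18 comparisons, and 2 tests for the 1 d comparison (the weak scan day as the whole cause, and genes recurring at 3 d), were chosen only after the results were seen. Among the values of the 20 marker genes and the share of probes above background, 61 values from 37 arrays lay far from the rest of their group by Dixon's test, in 441 tests of a measure within a group; chance alone gives about 1 in 20 tests, or 22. Values are log2 ratios of kidney over reference. Havcr1, the tubular injury marker KIM-1, stood apart at 3.37 on sham 0.5 h replicate 8, 2.93 on UUO 0.5 h replicate 2, 2.73 on UUO 1 h replicate 12, 0.50 on UUO 3 h replicate 16, 2.37 on UUO 5 h replicate 24, 3.12 on sham 7 h replicate 28, 3.12 on sham 3 d replicate 50, 0.94 on UUO 3 d replicate 46, 2.65 on UUO 5 d replicate 53 and 0.19 on sham 7 d replicate 58. Of these arrays, sham 0.5 h replicate 8 and UUO 1 h replicate 12 were the only ones of their groups with Y-linked RNA, and UUO 3 h replicate 16 and sham 7 d replicate 58 the only ones without; Havcr1 was 1.26 higher with such RNA. Lcn2, NGAL, stood apart at 1.27 on sham 12 h replicate 33 and 0.28 on UUO 3 d replicate 46. Spp1, osteopontin, stood apart at -1.34 on sham 0.5 h replicate 8, -1.50 on UUO 5 h replicate 24 and -0.23 on sham 5 d replicate 52, the only array of its group without Y-linked RNA, with which Spp1 was lower (-0.94). Clu, clusterin, stood apart at 2.39 on UUO 5 h replicate 22 and 2.59 on sham 7 h replicate 31. Col1a1, a chain of type I collagen, stood apart at -4.68 on UUO 3 h replicate 15. Col3a1, type III collagen, stood apart at -4.34 on UUO 3 h replicate 15 and -2.01 on sham 7 h replicate 32. Fn1, fibronectin, stood apart at -3.24 on sham 0 h replicate 4, -3.56 on UUO 0.5 h replicate 6, -3.24 on sham 3 h replicate 20 and -2.78 on sham 7 h replicate 32. Acta2, smooth muscle actin, stood apart at -1.33 on UUO 5 d replicate 51. Tgfb1, the profibrotic cytokine, stood apart at -0.35 on UUO 0.5 h replicate 1, -1.20 on UUO 3 h replicate 17, -0.26 on sham 3 d replicate 46 and -0.41 on sham 5 d replicate 54.

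Ccl2, a monocyte attractant, stood apart at -3.74 on sham 3 h replicate 18, -3.49 on sham 12 h replicate 35, -1.37 on UUO 3 d replicate 46 and -1.09 on UUO 5 d replicate 54. Fos, an immediate early gene, stood apart at -2.15 on sham 0.5 h replicate 5, -2.35 on sham 3 d replicate 46, -1.07 on UUO 3 d replicate 46, -3.65 on sham 5 d replicate 54 and -1.74 on UUO 7 d replicate 56. Egr1, an immediate early gene, stood apart at -4.99 on sham 1 d replicate 41. Atf3, a stress-induced factor, stood apart at -1.79 on sham 0 h replicate 4, 1.36 on UUO 7 h replicate 27 and -1.02 on sham 3 d replicate 46. Hmox1, heme oxygenase, stood apart at 1.14 on sham 7 h replicate 29, 0.06 on UUO 7 h replicate 26 and 0.91 on UUO 1 d replicate 40. Slc34a1, the phosphate transporter of the proximal tubule, stood apart at 7.22 on sham 0 h replicate 4, 6.48 on sham 7 h replicate 31, 6.30 on sham 3 d replicate 46, 5.30 on UUO 3 d replicate 46 and 5.52 on UUO 5 d replicate 53. Umod, uromodulin, stood apart at 4.70 on UUO 5 d replicate 53. Aqp2, the collecting duct water channel, stood apart at 1.42 on UUO 5 h replicate 22 and 2.38 on sham 3 d replicate 46. Egf, epidermal growth factor, stood apart at 5.69 on sham 0 h replicate 4, 7.49 on UUO 5 h replicate 23, 4.89 on sham 7 h replicate 31, 6.69 on sham 1 d replicate 40, 4.96 on sham 3 d replicate 46 and 4.55 on UUO 7 d replicate 57. Cd68, a macrophage marker, stood apart at -1.60 on sham 3 d replicate 46. The share of probes well above background was 72.3% on sham 3 h replicate 18.

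The UUO effect differed between early and late times for 8418 genes, by a test of the difference itself. Among the marker genes, the late effect differed from the early one for Havcr1 (1.5), Lcn2 (2.69), Spp1 (3.91), Clu (1.79), Col1a1 (2.75), Col3a1 (2.50), Fn1 (0.57), Acta2 (0.74), Tgfb1 (0.82), Ccl2 (0.83), Hmox1 (0.41), Slc34a1 (-0.59), Aqp2 (-1.03), Egf (-3.12), Mki67 (1.26) and Cd68 (0.99), on the log2 scale. The difference for Slc34a1 turned to 0.34 with the scanner's log ratio and with the series table, and its call was lost without any of 15 of the 116 arrays. Between 12 h and 1 d 1616 genes differed, among them Spp1 (2.51), Col1a1 (1.94), Col3a1 (1.71), Fn1 (1.20), Egf (-3.52) and Mki67 (1.80); of these only Egf kept its sign under median centring. With the scan day as a block Egf alone kept its call, and Spp1 (1.93, adjusted p = 0.0749), Col1a1 (1.32, adjusted p = 0.26), Col3a1 (1.14, adjusted p = 0.377), Fn1 (0.23, adjusted p = 0.785) and Mki67 (0.72, adjusted p = 0.681) lost theirs; with the slide as a block Egf lost its call as well (-0.95, adjusted p = 0.543). The call of Fn1 was lost for 9 and that of Mki67 for 11 of 24 arrays left out in turn. Between 1 d and 3 d 267 genes differed, among them Col1a1 (2.05), Col3a1 (1.90), Aqp2 (1.64) and Egf (1.89); the call was lost for 10 of 24 arrays left out in turn for Aqp2 and for 9 of 24 for Egf, and with the scan day as a block for Egf (1.67, adjusted p = 0.0503). With the slide as a block none of the 4 kept its call. Between 3 d and 7 d 510 genes differed, among them Col1a1 (1.54) and Hmox1 (-1.05); the call was lost for 15 of 23 arrays left out in turn for Col1a1 (highest adjusted p = 0.13) and for 16 of 23 for Hmox1 (highest adjusted p = 0.112). With the slide as a block Col1a1 (1.28, adjusted p = 0.0929) and Hmox1 (-0.98, adjusted p = 0.0725) lost their calls.

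A signal was also present in probes that carry no gene name. Of 3418 such probes that passed the same filter, 298 were higher and 415 lower in UUO at 7 d, or 713 in all; among 99 other splits of the 7 d arrays the highest count was 664.

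Other splits of the same arrays, 100 for each comparison with the real one counted, tested whether the number of genes could arise by chance. Chance was excluded at 7 h (668 genes, highest other split 394), 3 d (3702, 2065), 5 d (5154, 4227), 7 d (7484, 4464), for the mean over times (8074, 2990), for sham over time (7843, 2599) and for sham early against 0 h (1676, about 1.2e+02). At 12 h (2162, 4149) and for sham late against 0 h (2104, 2404) few splits gave as many genes, but some gave more. Chance is unlikely there and not excluded. For late minus early (8418, 2345), 1 d minus 12 h (1616, 2896) and 7 d minus 3 d (510, 497) the splits mixed times within each arm. They test whether either arm changes with time, and cannot exclude chance for a difference of the UUO effect. The splits with a count as large were 3 at 12 h, 4 for 1 d minus 12 h, 3 for sham late and 1, the real split, for the other comparisons named so far. The splits ignore scan day and slide, so that these stay a possible source of the counts where chance is unlikely. With the scan day and with the slide as a block the counts were 44 and 15 for 1 d minus 12 h, about 2.5e+02 and 27 for sham over time, 94 and 0 for sham early, and 0 and 0 for sham late. At 0.5 h (0 genes, highest other 1479), 1 h (0, 334) and 3 h (0, 3) the real count of 0 fixes the outcome, as any of the 100 splits gives as many, and the splits say nothing about chance. The splits did not make chance unlikely at 5 h (28, 5319, 9 splits) or at 1 d (6212, 11053, 10 splits). For 3 d minus 1 d (267, 3010, 5 splits) the splits also mixed times within each arm. They cannot test chance there for a difference of the UUO effect. As the splits ignore scan day, they cannot tell chance from scan day at 1 d. Splits with several times the real count, such as those at 5 h and for 3 d minus 1 d, point to a structure of the samples. At 1 d the split by the weak scan day gave 11053 genes and at 12 h it gave 7919; with the scan day in the model the real counts were 3433 and 2415.

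The first pattern weighed is the number of genes changed at 1 d, where 4 of 6 UUO arrays and 2 of 6 sham arrays came from the scan day of weak signal. That day as the whole cause is excluded, since 49.3% of the genes called at 1 d stayed called in the same direction with the scan day in the model (3065 of 6212). For the 3147 genes that lost their call, the median log2 fold change went from 0.55 to 0.26, or 46% of its size, while the median standard error went from 0.19 to 0.15; the size shrank, and for these genes weak signal and obstruction cannot be told apart, since they were picked by their loss. Obstruction remains possible for the other part, but its test cannot decide. Genes called at 1 d were called again at 3 d at 3.57 times the number of independent lists in the lower of the 2 directions. At both times 4 sham arrays and 1 UUO array came from scan day 7, so that a scan day effect could recur as well.

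The second pattern is that glucocorticoid and surgical stress genes were higher in early sham kidneys than at 0 h, with a list median of 1.03, 4 of 11 members called (6 over the list alone) and adjusted p = 0.0834 with an estimated correlation. The scan day is not the whole cause: within scan day 1, 5 early sham arrays against 3 arrays of 0 h gave a list median of 0.90, with 11 of 11 members higher. Among the 5 was sham 12 h replicate 33, with an array weight of 0.2. Slides were not kept apart in this test, and with the slide as a block the early comparison had 0 genes. Y-linked RNA on all 0 h arrays is not the whole cause either, as the median went from 1.03 to 0.76 with a term for it. Scan day and Y-linked RNA were not tested together, so that both combined are not excluded as the whole cause. A response to the operation that fades may be the cause, but cannot be told from scan day in the late times: the late median was -15.1% of the early one, or 61.8% with the scan day in the model.

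The third pattern is that the brown fat genes Cidea, Cox8b and Ucp1 were lower in the late than in the early UUO effect, by a mean log2 difference of -3.64 ± 0.77 (SE). The amount of fat left on the kidney was tested with 8 other adipocyte markers as a term. The difference was then -1.78 ± 0.29, so that it shrank and stayed below 0. The 8 markers stand for fat in general, and a different amount of brown fat could leave such a difference. The test therefore cannot exclude the amount of fat as the whole cause. No biological explanation was tested.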

How the results depend on the processing

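The fit without the weak scan day and the term for Y-linked RNA were tests chosen only after the results were seen. About 2.2e+02 named gene results passed in the reported model; without some single array 20 of them lost the call, and 0 reversed. The numbers that lost the call and that reversed were 0 and 0 with quantile normalization between arrays, which left the log ratios as they were, and 0 and 0 with outlier spots kept. They were 1 and 0 with array weights, 1 and 0 with a trended and robust prior, 3 and 0 with no background subtraction, 4 and 0 with no filter, 4 and 0 with the Y-linked term and 7 and 0 with a mean over probes. They were 12 and 2 with Cy5 alone, 12 and 4 with the scanner's log ratio, 12 and 4 with the series table, 25 and 0 without the weak scan day, 26 and 0 with the scan day as a block, 52 and 2 with the slide as a block and 72 and 11 with median centring. With the strict filter they were 0 and 0 of 119 results with a value, and with arrays of a single time they were 19 and 0 of about 1.4e+02. Of the list tests, camera called 237 with its preset correlation and 52 with an estimated one, and fry called about 2.2e+02.

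Counts of changed genes were as follows in the reported model: 0 (0.5 h), 0 (1 h), 0 (3 h), 28 (5 h), 668 (7 h), 2162 (12 h), 6212 (1 d), 3702 (3 d), 5154 (5 d), 7484 (7 d), 8074 (the mean over times), 8418 (late minus early), 1616 (1 d minus 12 h), 267 (3 d minus 1 d), 510 (7 d minus 3 d), 7843 (sham over time), 1676 (sham early against 0 h), 2104 (sham late against 0 h). Counts written with e+02 are rounded to 2 digits. The counts that differed from these by more than 1.5 times are given by setting, and their cause was not tested except where stated. No background subtraction gave 1013 (7 h), 4117 (1 d minus 12 h) and 1232 (3 d minus 1 d). The scanner's log ratio gave 67 (5 h), 4640 (12 h), 2901 (1 d minus 12 h) and 1980 (3 d minus 1 d). The series table gave 67 (5 h), 4638 (12 h), 2904 (1 d minus 12 h) and 1988 (3 d minus 1 d). Cy5 alone gave 3 (0.5 h), 84 (5 h), 4013 (12 h), 1846 (3 d minus 1 d), 771 (7 d minus 3 d), 4195 (sham over time), 430 (sham early against 0 h) and 852 (sham late against 0 h). Median centring, which removes no dye bias that varies with intensity, gave 0 (5 h), 19 (7 h), 247 (12 h), 492 (3 d), 1313 (5 d), 1991 (7 d), 2170 (the mean over times), 2422 (late minus early), 11974 (1 d minus 12 h), 1.1e+02 (3 d minus 1 d), 8 (7 d minus 3 d), 13447 (sham over time) and 293 (sham early against 0 h). The strict filter tests 5348 genes, fewer than the 17685 of the reported model, and gave 333 (7 h), 2770 (1 d), 2125 (3 d), 2494 (5 d), 3180 (7 d), 3475 (the mean over times), 3399 (late minus early), 909 (1 d minus 12 h), 314 (7 d minus 3 d), 3179 (sham over time), 912 (sham early against 0 h) and 1177 (sham late against 0 h). No filter gave 1 (0.5 h). Array weights gave 504 (0.5 h), 1 (1 h), 6 (3 h), 1.6e+02 (5 h), 1816 (7 h), 8358 (12 h), 12704 (1 d), 6033 (3 d), 8723 (5 d), 12195 (1 d minus 12 h), 9558 (3 d minus 1 d), 2978 (7 d minus 3 d), 15852 (sham over time), 7281 (sham early against 0 h) and 7560 (sham late against 0 h).

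The slide as a block gave 1 (3 h), 1481 (1 d), 1505 (3 d), 5211 (late minus early), 15 (1 d minus 12 h), 1398 (7 d minus 3 d), 27 (sham over time), 0 (sham early against 0 h) and 0 (sham late against 0 h). The scan day as a block gave 3433 (1 d), 44 (1 d minus 12 h), 948 (7 d minus 3 d), 2.5e+02 (sham over time), 94 (sham early against 0 h) and 0 (sham late against 0 h). Arrays of a single time gave 0 (5 h), 733 (12 h) and 2259 (1 d). These are the times that held arrays of the weak scan day. In that setting the spread came from the arrays of that time alone, and in the reported model from all arrays. Without the weak scan day the counts were 1 (3 h), 1010 (7 h), 2932 (1 d), 94 (1 d minus 12 h), 1183 (7 d minus 3 d) and 3208 (sham late against 0 h). The term for Y-linked RNA gave 427 (3 d minus 1 d). The replicate numbers do not pair the arrays; the replicate block gave 902 (7 d minus 3 d).

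With single arrays left out, the counts ranged over 0 to 255 (0.5 h), 0 to 0 (1 h), 0 to 0 (3 h), 10 to 43 (5 h), 463 to 731 (7 h), 1569 to 2691 (12 h), 4462 to 7878 (1 d), 3054 to 4368 (3 d), 4266 to 5502 (5 d), 6695 to 7474 (7 d), 7825 to 8439 (the mean over times), 8079 to 8883 (late minus early), 534 to 4318 (1 d minus 12 h), 1.7e+02 to 868 (3 d minus 1 d), 2.3e+02 to 713 (7 d minus 3 d), 6368 to 9296 (sham over time), 416 to 2448 (sham early against 0 h), 877 to 2781 (sham late against 0 h).

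Directions turned as follows, and the cause was not tested. With median centring: Ccl2 -0.83 (1 d), Cd68 -0.22 (1 d), Egr1 -0.11 (1 d), Fn1 -0.85 (1 d), Mki67 -0.40 (1 d), Tgfb1 -0.21 (1 d), Col1a1 -1.15 (1 d minus 12 h), Col3a1 -1.37 (1 d minus 12 h), Fn1 -1.54 (1 d minus 12 h), Mki67 -1.09 (1 d minus 12 h) and Spp1 -1.90 (1 d minus 12 h). With the scanner's log ratio: Slc34a1 1.52 (1 d), Tgfb1 -0.15 (1 d), Slc34a1 0.01 (the mean over times) and Slc34a1 0.34 (late minus early); with the series table: Slc34a1 1.51 (1 d), Tgfb1 -0.15 (1 d), Slc34a1 0.01 (the mean over times) and Slc34a1 0.34 (late minus early). With Cy5 alone: Tgfb1 -0.06 (1 d), Umod -0.90 (1 d) and Spp1 -0.03 (1 d minus 12 h). With the slide as a block: Slc34a1 0.27 (1 d) and Fn1 -0.01 (1 d minus 12 h). Umod at 1 d had not passed in the reported model.

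Median centring moved the median of all genes by -0.585 at 1 d, 0.48 at 12 h, -1.108 for 1 d minus 12 h, 0.684 for 3 d minus 1 d and 0.334 for sham late against 0 h, and the scanner's log ratio moved it by -0.11 at 1 d. The share of changed genes that rose was 100% (7 h, 56.6% in the reported model), 87% (12 h, 36.4% in the reported model), 12.5% (1 d, 42.6% in the reported model), 78.3% (3 d, 53.4% in the reported model), 88.7% (5 d, 49.9% in the reported model), 60.1% (7 d, 44.7% in the reported model), 16.2% (1 d minus 12 h, 69.7% in the reported model), 99.1% (3 d minus 1 d, 78.7% in the reported model), 87.5% (7 d minus 3 d, 66.1% in the reported model), 44.7% (sham early against 0 h, 33.8% in the reported model) and 54.3% (sham late against 0 h, 35.2% in the reported model) with median centring. It was 74.6% (5 h), 52% (12 h), 30% (1 d minus 12 h) and 49.4% (sham late against 0 h) with the scanner's log ratio, 74.6% (5 h), 52% (12 h), 30% (1 d minus 12 h) and 49.3% (sham late against 0 h) with the series table, 64.3% (5 h), 32.6% (1 d minus 12 h), 47% (sham early against 0 h) and 50% (sham late against 0 h) with Cy5 alone and 55.6% (1 d minus 12 h) and 78.1% (7 d minus 3 d) with no background subtraction. Signal over background limits the 16 arrays of the weak scan day most, on which 17.2% to 42.0% of probes stood well above background.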

Other observations

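The term for Y-linked RNA and the look at single arrays were tests chosen after the data were seen. Arrays were sorted by their Y-linked RNA, so that a difference in Ddx3y, a Y-linked gene, was fixed in advance. Kidneys with and without RNA of Y-linked genes differed in many genes: in a model with the 21 groups and a single term for such RNA, without its interaction with the operation, 2821 genes were higher and 4173 lower on the 63 arrays with such RNA (limma, adjusted p under 0.05). Beside Xist (-5.85 ± 0.24, SE, log2, adjusted p = 1.11e-40), the RNA that silences an X chromosome, and Ddx3y (4.02 ± 0.13, adjusted p = 2.87e-48), the genes Acsm3, an acyl-CoA synthetase (5.97 ± 0.20, adjusted p = 1.51e-48), Slc7a13, an amino acid transporter (5.46 ± 0.28, adjusted p = 7.21e-33), and Cyp2j13, a cytochrome P450 (5.40 ± 0.21, adjusted p = 9.88e-42), were higher, and Slc7a12, a related transporter (-3.66 ± 0.33, adjusted p = 4.43e-17), Abcc3, an organic anion pump (-2.58 ± 0.13, adjusted p = 1.42e-32), and Prlr, the prolactin receptor (-2.53 ± 0.21, adjusted p = 7.56e-19), were lower. Of the marker genes, Havcr1 was higher (1.26 ± 0.17, adjusted p = 4.39e-09) and Spp1 (-0.94 ± 0.09, adjusted p = 7.63e-17), Clu (-0.32 ± 0.06, adjusted p = 1.05e-05) and Acta2 (-0.19 ± 0.07, adjusted p = 0.0384) were lower; Cd68 was higher by 0.26 ± 0.10 (adjusted p = 0.031).

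At 3 d, UUO replicate 46 and sham replicate 46, arrays of opposite arms scanned on the same day, deviated from their groups in the same way, with a correlation of 0.88 over 17033 genes. Their log2 ratios were compressed, with slopes of 0.37 and 0.59 on the mean of the other arrays of their group. On them Xist was -1.52 and -3.16 and Ddx3y 0.41 and 1.17.

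At 7 d the brown fat gene Cidea was -2.89, Cox8b -3.19 and Ucp1 -2.13 on the log2 scale, and Adipoq -0.84, while Dio2, a thyroid hormone deiodinase, was 3.33. The differences among these genes were not tested, and the genes were picked after their values were seen. The median correlation between adipocyte markers over arrays was 0.75.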
